A study of Saccharomyces cerevisiae with 2 samples.

How the data were processed

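RNA from 2 replicate yeast cultures of the histone H3 K4, K36 and K79 to arginine mutant, 12 h after the move from galactose to glucose, was measured on an array per culture. Per the labels' protocols, total RNA was extracted with hot acid phenol and chloroform, and about 20 ug was made into biotin-labelled cRNA. The series' design text speaks of replicate cultures. The deposited values are intensity values on a linear scale, a single signal per probe set, made with MAS5 per the submitters' processing notes. The MAS5 version and its settings are not given in the sources used here, and detection calls were not used here. On each array all deposited intensity values were whole multiples of a single step (0.0639 on replicate 1 and 0.0617 on replicate 2, within a tolerance of 0.02 steps), so a single factor per array had been applied. What that factor was set on is not given in the sources used here.

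The arrays held 9335 probe sets, with values of 0 for 29 on replicate 1 and 26 on replicate 2. Signal over background was read from control probe sets. The 4 mouse controls, with no match in yeast, gave at most 0.511 on replicate 1 and 1.30 on replicate 2, and 8997 and 8760 probe sets lay above these levels. The 9 probe sets for the opposite strand of the E. coli controls read up to 3.39 and 4.07. Lying above the mouse controls therefore does not by itself show signal. The 15 Bacillus poly-A control probe sets had a mean log2 ratio of replicate 2 to replicate 1 of -0.0094 (SD 0.053), and the 9 E. coli hybridisation controls -0.11 (SD 0.11). The 3' to 5' signal ratios were 1.29 and 1.43 for ACT1, 2.44 and 2.73 for SPT15, and 2.27 and 2.81 for SRB4 on replicates 1 and 2. The number of arrays limits the precision of every value.

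Probe sets were named through the platform annotation, updated by gene identifier to RefSeq's table of the R64 assembly. Of the probe sets, 60 are controls, 6504 had 1 gene and all of these matched the table, 328 had several genes and were not named, and 2443 are unnamed here. The named probe sets cover 5656 genes, of which 314 have over 1 probe set. A gene's value was the mean of its probe sets' log2 signals, with values of 0 left out. Chromosomes were taken from the systematic names.

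The comparisons, 43 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The 2 arrays form 1 group, so no test between groups was made. Agreement was described by the log2 ratio of replicate 2 to replicate 1. Genes with a mean log2 signal at or above the 25th percentile (4242 genes) entered the counts at 2-fold, the list shifts and the chromosome shifts. A list's median signal was placed among 10000 random lists of the same size drawn from all genes. A list's median log2 ratio, relative to that of all kept genes, was placed among 10000 random lists matched on signal in 20 bins. Lists with under 3 genes were not placed, which leaves 42 lists for signal and 38 for shifts. The percentiles describe these 2 arrays and are not p-values. Named genes were the first 3 measured members of each list, the core histones, the 3 members farthest in the direction of each list outside the central 95%, the 10 genes with the largest and the 10 with the smallest ratio, and the 10 brightest. Not all of them are printed. Other genes were named after their values were seen.

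The steps were tested on simulated data with independent normal noise, its SD taken from the median absolute deviation of the real ratios in each signal bin. Such noise lacks the long tails of the real ratios and the correlation between probe sets of nearby numbers. The rates below therefore need not hold for real arrays. For the 2-fold counts over 4242 genes, 0.5% of genes changed 1.5-fold, 97.5% of those changed 2.5-fold and 100% of those changed 3-fold were recovered, with 0 false calls. For list shifts, 4 of 5 lists of 30 genes moved by -0.1 and 5 of 5 moved by -0.2 fell below the central 95%, and 4 of 40 lists fell outside it with no shift. Alternatives were quantile normalisation, centring on the median, loess, other signal filters, pseudocounts, plain probe sets only, list means and other fold sizes. Leaving out a replicate was tried for list signal. Alternatives added after seeing the data were leaving out the probe set numbers around the low genes, a correction by probe sets 69 to 71 numbers away and at about double that distance, a gene length correction, scaling on the poly-A controls and a pseudocount of 1. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.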

Results

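The series measured RNA levels in budding yeast (Saccharomyces cerevisiae) in which lysines 4, 36 and 79 of histone H3 were replaced by arginine. These lysines are the sites methylated by the enzymes Set1, Set2 and Dot1, and arginine at these sites cannot be methylated by them. Per the series' design text, a wild-type H3 gene was active in galactose and was repressed by moving the cells to glucose, to leave the mutant gene as the source of H3. Cells were taken 12 h after the move, at an optical density of 0.5 to 0.7. Total RNA from 2 replicate cultures was labelled with biotin and hybridised to an Affymetrix yeast expression array each. Both arrays belong to a single group, and the wild-type strain and the other times of the series' design were not analysed here. No difference between mutant and wild type can therefore be given, and the values describe the mutant at 12 h and how closely its 2 cultures matched. Each array gave a signal for 9335 probe sets, with a median of 28.4 on replicate 1 and 27.5 on replicate 2. Errors are SD over the 2 arrays (n = 2), and this number of arrays limits their precision.

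The first question is which genes gave strong and weak signal in the mutant 12 h into glucose. Genes of glycolysis and fermentation had the highest median signal of the fixed gene lists, 1419 ± 28.9 (SD, n = 2) over 15 genes, against 41.8 for the median of all genes. Ribosomal protein genes followed, at 867 ± 53.9 over 81 genes, a list chosen by name that also took in the RNase P gene RPP1, at 38.5 ± 2.20. Genes of meiosis and sporulation, which are silent in growing haploid cells, had the lowest, at 5.53 ± 0.138 over 23 genes. Of 42 lists placed against 10000 random lists of the same size, 18 lay above the central 95% and 3 below. Signal also depends on how well each probe set hybridises, so lists were placed against the array and single genes were not compared with each other.

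Among carbon metabolism genes, the glyceraldehyde phosphate dehydrogenase gene TDH3 had a signal of 1473 ± 0.650, the enolase gene ENO2 1521 ± 8.31 and the phosphoglycerate kinase gene PGK1 1532 ± 16.2. The hexose transporter genes had a median of 145 ± 10.6 over 9 genes, above 99.0% of random lists. HXT1 had 145 ± 10.6, HXT2 434 ± 30.2 and HXT3 1031 ± 57.6. With plain probe sets only, the hexose transporter list lay at percentile 92.9, inside the central 95%. The galactose regulon, whose promoters Gal4 activates in galactose, had a median of 17.3 ± 2.99 over 7 genes and lay at percentile 4.66, inside the central 95%. The galactokinase gene GAL1 had 8.20 ± 0.248, GAL7 17.3 ± 2.99 and GAL10 29.8 ± 1.79. Glucose-repressed carbon genes had a median of 36.9 ± 1.27 over 17 genes and lay at percentile 35.7. Within that list, the alcohol dehydrogenase gene ADH2 had 236 ± 2.60, the fructose bisphosphatase gene FBP1 21.4 ± 0.843 and the gluconeogenic gene PCK1 78.1 ± 10.2.

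Growth genes were bright. RPL3 had 790 ± 3.88, RPS3 1481 ± 23.3 and RPL25 954 ± 4.72. Translation factors had a median of 275 ± 10.7 over 16 genes, above all random lists, with the elongation factor gene YEF3 at 1309 ± 52.4, EFB1 at 885 ± 31.1 and the initiation factor gene TIF11 at 258 ± 19.3. Ribosome biogenesis genes had a median of 72.3 ± 0.889 over 76 genes, above 99.9% of random lists, with the nucleolar genes NOP1 at 389 ± 9.06, NSR1 at 273 ± 22.7 and GAR1 at 220 ± 28.2. Placed only against genes that passed the signal filter, this list lay at percentile 89.5. Genes of RNA polymerase I and III had a median of 71.3 ± 0.00717 over 18 genes and stayed inside the central 95%. Their large subunit genes RPA190 and RPA135 had 27.9 ± 2.78 and 222 ± 5.76, and RPA49 had 133 ± 4.68. The 7 RPA190 probe sets disagreed, from 3.45 to 196 on replicate 1.

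Respiratory genes encoded in the nucleus were also bright on both arrays. Nuclear genes of oxidative phosphorylation had a median of 323 ± 11.1 over 30 genes, and genes of the tricarboxylic acid cycle 284 ± 0.219 over 15 genes, each above all random lists. The ATP synthase gene ATP1 had 533 ± 20.9, COX4 305 ± 5.28 and QCR2 413 ± 25.6. The citrate synthase gene CIT1 had 520 ± 10.8, the aconitase gene ACO1 571 ± 68.2 and KGD1 265 ± 6.25. The 8 protein genes of the mitochondrial genome had a median of 9.96 ± 1.89 and lay at percentile 0.26, with COX1 at 64.6 ± 1.29, COX2 at 6.46 ± 1.63 and COX3 at 15.4 ± 7.40. The 3 COX1 probe sets disagreed, at 824, 11.4 and 27.4 on replicate 1. With plain probe sets only, this list lay at percentile 3.24, inside the central 95%. How the labelling treats mitochondrial RNA was not examined, so the low signal is not read as a low RNA level. Genes of the mitochondrial ribosome had a median of 55.4 ± 2.04 over 56 genes, at percentile 92.6.

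Stress genes and biosynthetic genes filled most of the other places above the random range. Heat shock proteins and chaperones had a median of 304 ± 26.6 over 22 genes, general stress and reserve carbohydrate genes 180 ± 9.32 over 24 genes and oxidative stress genes 263 ± 14.7 over 16 genes. HSP104 had 270 ± 37.6, HSP82 343 ± 12.3 and SSA4 216 ± 8.74. The small heat shock gene HSP12 had 1264 ± 64.8, the catalase gene CTT1 50.5 ± 4.43 and the peroxiredoxin gene TSA1 1280 ± 4.65. Amino acid biosynthesis genes had a median of 334 ± 12.6 over 35 genes, purine biosynthesis genes 359 ± 16.05 over 13 genes and ergosterol biosynthesis genes 323 ± 35.0 over 25 genes. HIS4 had 460 ± 26.1, ADE1 495 ± 34.3 and ERG11 684 ± 18.9. Cell wall genes had a median of 385 ± 12.0 over 22 genes and proteasome genes 191 ± 18.4 over 33 genes. The cell wall list, chosen by name, also took in MLP1, which is not a cell wall gene. CCW12, a cell wall mannoprotein gene, had 1922 ± 3.80. M/G1 cell cycle genes had a median of 115 ± 3.46 over 12 genes, at percentile 99.2, with the chitinase gene CTS1 at 630 ± 13.7. Seripauperins, at 99.98 ± 0.622 over 11 genes, and selectable marker genes, at 137 ± 2.02 over 7 genes, lay just above the random range, at percentiles 97.9 and 97.8. Both lay inside the central 95% on replicate 1 alone (percentiles 97.24 and 97.44) and with the list mean (97.41 and 97.23), and seripauperins also on replicate 2 alone (97.38). Placed only against genes that passed the filter, the M/G1, seripauperin and marker lists lay inside it at percentiles 95.2, 91.1 and 93.6.

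Lists of chromatin genes gave moderate median signal. The methylation machinery for the 3 substituted lysines had a median of 31.8 ± 0.320 over 18 genes and lay at percentile 19.1, inside the central 95%. SET1, the gene of the K4 methyltransferase, had 42.6 ± 6.34, SET2, that of the K36 enzyme, 4.94 ± 0.789, and DOT1, that of the K79 enzyme, 16.6 ± 1.30. SET2, at 5.50 and 4.38 on replicates 1 and 2, lay little above the opposite-strand E. coli controls, which read up to 3.39 and 4.07. The Rpd3 deacetylase complexes had a median of 33.1 ± 0.397 over 14 genes, silencing factors 37.6 ± 7.37 over 7 genes and the SAGA, TFIID and remodeler list 29.9 ± 0.787 over 31 genes, all inside the central 95%. RPD3 had 56.4 ± 2.06, SIR2 56.1 ± 1.62, SIR3 43.7 ± 0.912 and SIR4 20.2 ± 0.947. Histone chaperones and elongation factors had a median of 42.1 ± 2.11 over 17 genes, and RNA polymerase II and mediator genes 44.6 ± 1.51 over 32 genes. The variant histone genes HTZ1 and CSE4 had 82.0 ± 0.579 and 27.9 ± 2.43, and the linker histone gene HHO1 had 71.6 ± 1.24.

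Of the core histone genes, HTB1 and HTB2, which encode H2B, had probe sets of their own, with 493 ± 8.84 and 312 ± 4.87. The probe sets of H3, H4 and H2A each match both gene copies. The 3 H3 probe sets read 1711 ± 2.83, 147 ± 13.7 and 2.41 ± 1.92, the H4 probe set 383 ± 6.11, and the H2A probe sets 874 ± 32.5 and 607 ± 21.1. The H3 probe sets are not assigned here to mutant or wild-type transcript, so they do not check whether the wild-type gene was shut off.

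Meiosis and COS genes lay below the random range. IME1, the inducer of meiosis, had 13.8 ± 0.609, NDT80 5.87 ± 2.28 and SPO11 4.42 ± 1.71. The COS list had a median of 11.3 ± 0.360 over 8 genes, at percentile 0.31, with COS10 at 1.86 ± 0.113 and COS12 at 5.61 ± 1.06. The COS family is found near chromosome ends, but the list, chosen by name, also took in COS111, at 3.34 ± 0.705, which is not of that family. Placed only against genes that passed the filter, the 3 remaining genes of the list lay at percentile 73.8. COS10 on both arrays, and SPO11 and COS111 on replicate 2, lay within the range of the opposite-strand E. coli controls, up to 3.39 and 4.07. Genes specific to mating type a had a median of 93.7 ± 3.13 over 7 genes and those specific to mating type alpha 14.9 ± 1.18 over 4 genes, at percentiles 93.4 and 5.16. The alpha-factor receptor gene STE2 had 96.3 ± 0.530, and the a-factor receptor gene STE3 had 8.06 ± 0.465. The remaining lists stayed inside the central 95%. These were G1/S and G2/M cell cycle genes, DNA damage genes, sulfur, phosphate and iron genes, flocculins, and haploid-specific and pheromone genes.

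**Figure D1:**
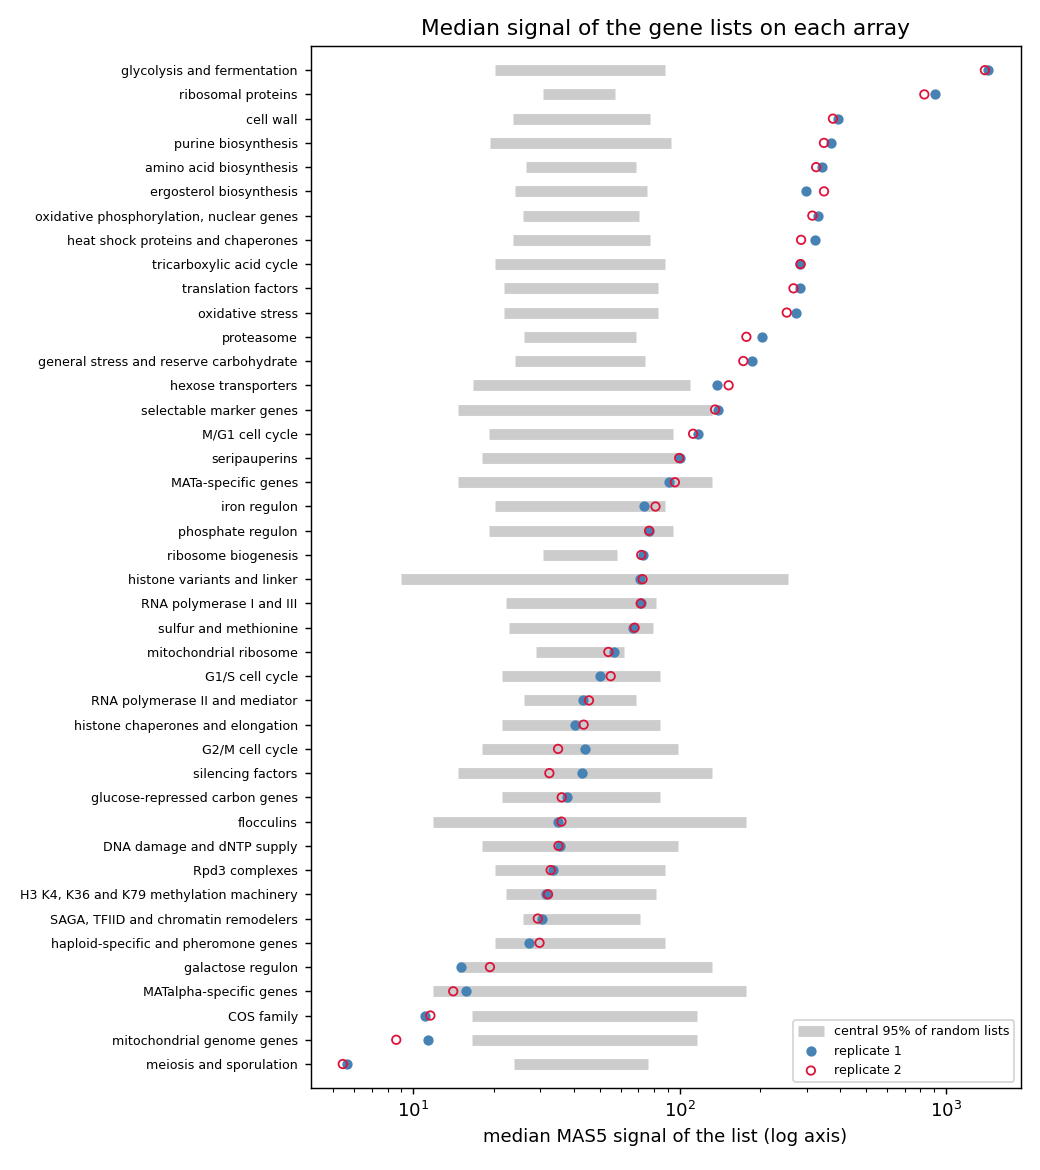
Median MAS5 signal of each of 42 gene lists (log axis, arbitrary units) on replicate 1 (filled points) and replicate 2 (open points), with the central 95% of 10000 random lists of the same size as grey bars. Glycolysis and fermentation lies highest at 1419, and meiosis and sporulation lowest at 5.53.

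The second question is how closely the 2 cultures matched. RNA levels were close. Among the 4242 genes kept by the signal filter, 89.6% differed by less than 1.2-fold. Of the 10 brightest genes, CCW12 was 1924 and 1919, RPS22A 1912 and 1910, the triose phosphate isomerase gene TPI1 1670 and 1582 and the cell wall gene SED1 1627 and 1472 on replicates 1 and 2. Saturation at the top of the signal range was not examined. The log2 ratio of replicate 2 to replicate 1 had a median of -0.023, an SD of 0.20 and a central 95% from -0.43 to 0.31. Across genes, log2 signals of the 2 arrays had a Pearson correlation of 0.990 and a Spearman correlation of 0.984, and genes are not independent replicates. A rescaled copy of an array would have given the same ratio for every gene, which this spread rules out. The genes under the filter, below a signal of about 19.2, had an SD of 0.45.

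**Figure D2:**
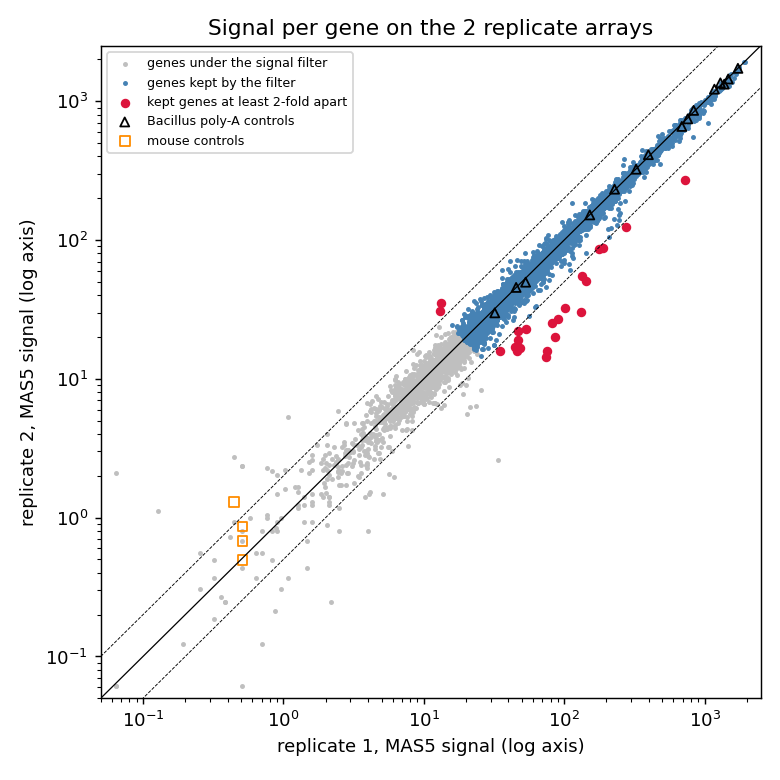
MAS5 signal of each gene on replicate 1 (x axis) and replicate 2 (y axis), both log axes in arbitrary units, with genes under the filter in grey, kept genes in blue, kept genes at least 2-fold apart in red, Bacillus poly-A controls as triangles and mouse controls as squares; the solid line marks equal signal and the dashed lines 2-fold. The 20 genes below the lower dashed line and the 2 above the upper one are the only kept genes past 2-fold.

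At a fixed size of 2-fold, 20 kept genes were lower on replicate 2 and 2 were higher. The lowest were ERG29, an ergosterol gene, at 74.3 on replicate 1 and 14.3 on replicate 2, SDD2 at 75.6 and 15.8, the translation termination factor gene SUP35 at 132 and 30.4, and the mitochondrial ribosomal gene RSM10 at 86.0 and 20.0. STE23 was at 91.0 and 27.2, the ubiquitin-like protein gene RUB1 at 81.3 and 25.1, SPC2 at 101 and 32.3, MLO1 at 45.9 and 15.8, NGL2 at 48.3 and 16.7, and the transcription coactivator gene SUB1 at 143 and 50.3. These 20 genes share no fixed list as a group. Instead, 10 lie on chromosome 4, 9 on chromosome 13 and 1 on chromosome 12, and their probe sets carry numbers from 6178 to 6594 and from 9334 to 9924. The RUB1 probe sets gave log2 ratios of -0.52 and -2.87. The 2 higher genes rest on disagreeing probe sets. The 25S ribosomal RNA gene RDN25-1 had log2 ratios of 0.047 and 2.73, and the aldehyde dehydrogenase gene ALD6 read 0.447 and 2.65 on a dim probe set but 383 and 360 on a bright one. The next highest were SNR4, a small nucleolar RNA, with a log2 ratio of 0.79, RGL1 with 0.75, YLR264C-A with 0.71, CUE3 with 0.68 and KAP114 with 0.64, followed by UTP18, GPR1 and EXG2 with 0.63, 0.62 and 0.61. With 1 array against 1 array there is no replicate check on any of these differences and no p-value is given.

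**Figure D3:**
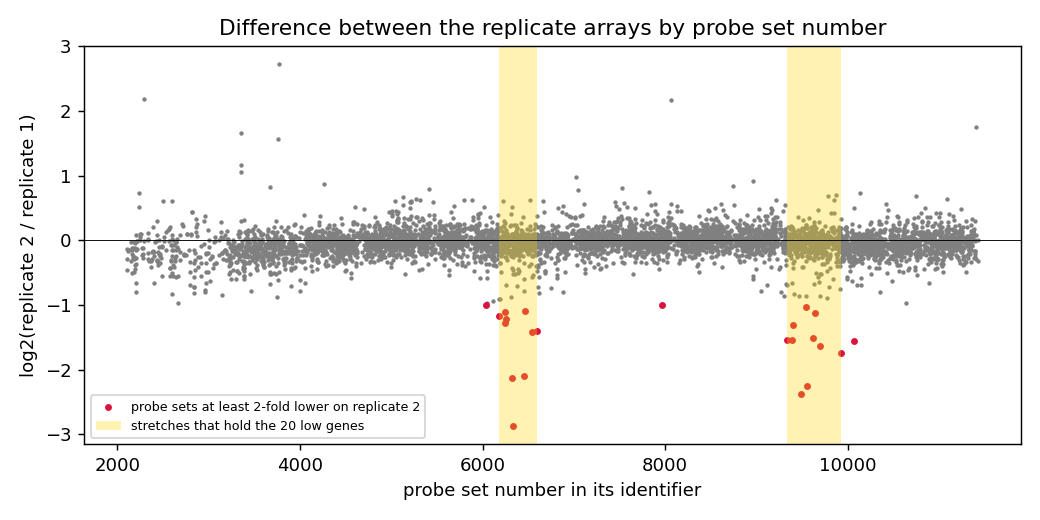
Log2 ratio of replicate 2 to replicate 1 for each probe set with a signal of at least 16 (y axis) against the number in the probe set's identifier (x axis), with probe sets at least 2-fold lower in red. The probe sets of the 20 low genes lie in 2 stretches, 6178 to 6594 and 9334 to 9924, shaded yellow.

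Differences were next summed over gene groups. Genes of purine biosynthesis, glucose-repressed carbon use, nuclear oxidative phosphorylation, the mitochondrial ribosome and the cytosolic ribosome were slightly lower on replicate 2. Their median log2 ratios, relative to all kept genes, were -0.12, -0.11, -0.058, -0.047 and -0.044. In purine biosynthesis 11 of 13 genes lay below the median ratio of all kept genes, with the first-step enzyme gene ADE4 at 110 on replicate 1 and 60.7 on replicate 2, IMD4 at 371 and 285 and IMD3 at 681 and 586. The IMD4 probe sets disagreed, with log2 ratios of 0.097 and -0.85. ADE4, IMD4 and IMD3 have probe sets among the numbers around the low genes. Without those numbers the purine biosynthesis shift was -0.085 over 7 genes at percentile 4.65, and with plain probe sets only it was -0.084 at percentile 2.81, both inside the random range, so a part from array position stays open. In the glucose-repressed list 10 of 13 lay below that median, with the glyoxylate cycle genes MLS1 at 82.2 and 56.0 and ICL1 at 71.6 and 52.4, and the peroxisomal gene FOX2 at 32.7 and 25.2.

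In the ribosomal protein list 54 of 81 genes lay below the median ratio of all kept genes, with RPS29B at 726 and 273, RPL38 at 831 and 550 and RPL37B at 1050.4 and 700.4. In nuclear oxidative phosphorylation 23 of 30 lay below that median, with the ATP synthase subunit genes ATP17 at 169 and 132, ATP14 at 188 and 157 (2 probe sets, 349 and 101 on replicate 1) and ATP20 at 99.5 and 86.6. In the mitochondrial ribosome 37 of 54 did, with MRPL7 at 46.6 and 19.1, MRPS5 at 24.99 and 19.7 and MRPL15 at 44.4 and 35.3. MRPL7 and RPS29B are among the 20 low genes. These 5 lists lay below the central 95% of random lists matched on signal and none of 38 lay above, where about 1.9 outside are expected by chance. In simulated data without any shift, 4 of 40 lists of 30 genes fell outside. The lists kept their sign under every setting tried, but each lost its place outside the random range under at least 1 setting. With plain probe sets only, the ribosomal protein shift was -0.016 over 53 genes at percentile 21.5. After a correction for neighbouring probe sets, added after seeing the data, the glucose-repressed shift was -0.042 at percentile 19.2.

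The lists tied to the substituted lysines lay inside the random range. The methylation machinery had a shift of 0.082 over 12 kept genes (percentile 93.1). SET2 and DOT1 were under the filter and did not enter it, and the log2 ratios of SET1, SET2 and DOT1 were -0.31, -0.33 and -0.16, opposite to the list. SET2 read little above the opposite-strand E. coli controls, so its ratio says little. RCO1 of the Rpd3 complexes, whose probe set lies among the numbers around the low genes, was also under the filter. It read 20.5 and 5.62 (log2 ratio -1.86), and a part from array position stays open. The Rpd3 complexes had a shift of 0.0016 over 10 genes without it (percentile 48.2) and silencing factors -0.066 over 6 (percentile 18.5). Translation factors had a shift of -0.052 (percentile 6.96), with 13 of 16 genes below the median ratio of all kept genes. They lay outside with the list mean (-0.17, percentile 0.09) and with the correction for neighbouring probe sets (-0.092, percentile 0.36). The list mean takes in SUP35, 1 of the 20 low genes, with a log2 ratio of -2.12, so it does not show a drop across the list. Glycolysis and fermentation had 0.012 over 15 genes and the galactose regulon 0.15 over 3 genes, also inside.

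**Figure D4:**
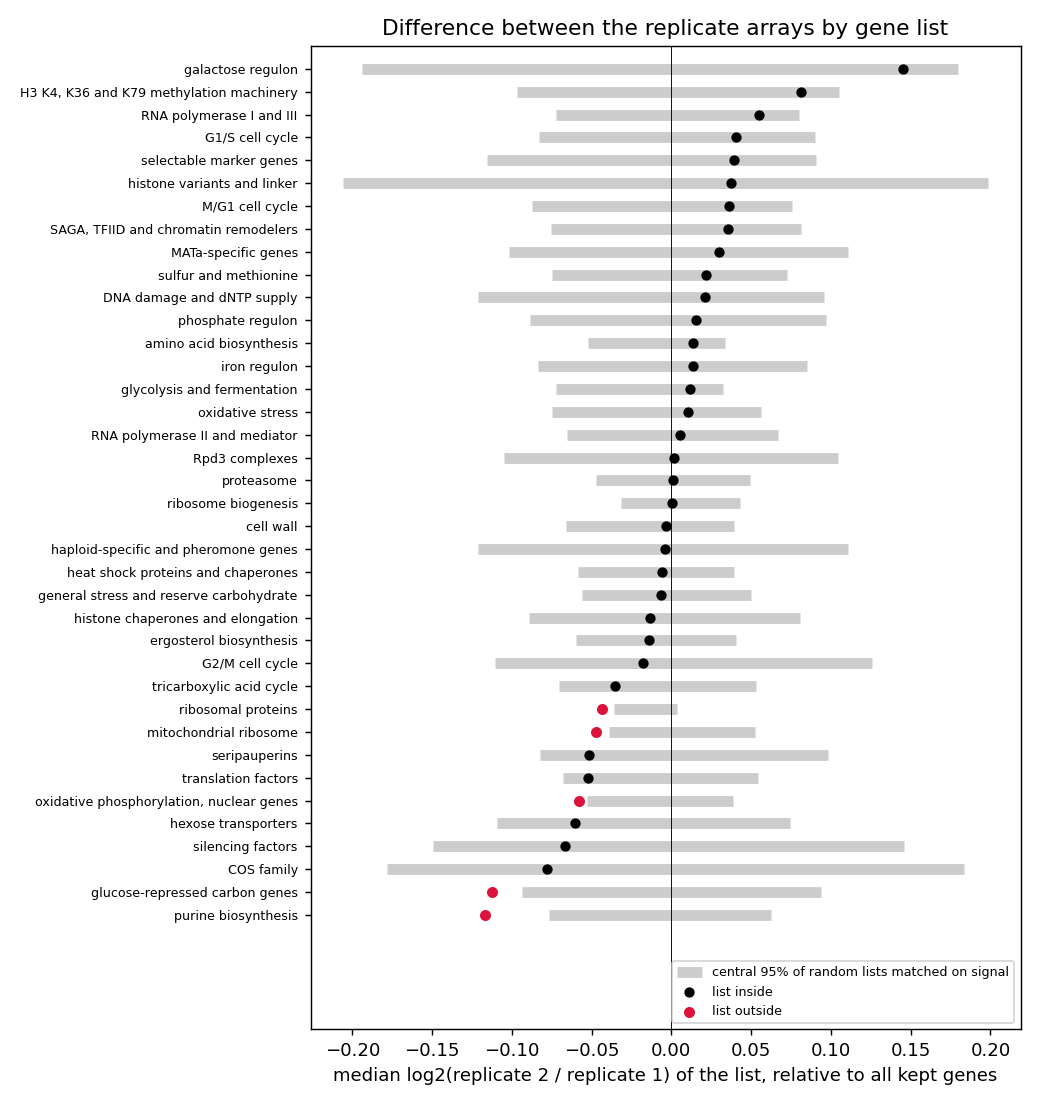
Median log2 ratio of replicate 2 to replicate 1 of each of 38 gene lists, relative to all kept genes (x axis), with the central 95% of 10000 random lists matched on signal as grey bars, lists inside in black and lists outside in red. The 5 lists outside all lie on the lower side, between -0.12 and -0.044.

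Chromosomes were compared in the same way, since a gained or lost chromosome in a culture would move its genes together. Genes of chromosomes 4, 8, 11, 12 and 13 were lower on replicate 2 than random lists and those of chromosomes 2, 14, 15 and 16 were higher. The sizes were small: the lowest was -0.061 for the 357 genes of chromosome 12 and the highest 0.043 for the 378 genes of chromosome 15. Of the outermost 10 genes of each chromosome arm, where Sir silencing acts, the 187 kept by the signal filter had a shift of 0.0012, at percentile 55.7. Dimmer genes there did not enter, so the value does not cover genes with little signal. Chromosome 4 lay inside the random range with quantile normalization, loess and plain probe sets (percentiles 3.17, 4.21 and 5.72) and with the gene length correction (9.45), which placed chromosome 5 above (98.99). Chromosome 13 lay inside with no filter and with the filter at the median (4.97 and 10.3), and the list mean placed chromosomes 5 and 7 above (99.6 and 99.99). With the correction for neighbouring probe sets, chromosome 8 stayed below the random range, chromosome 6 was newly below, and 0 lay above. Chromosomes 2, 4, 12 and 13 then lay well inside, at percentiles 82.5, 40.1, 13.5 and 16.3, with chromosome 12 at -0.011, and chromosomes 11, 14, 15 and 16 lay near the limits, at 2.54, 96.9, 97.1 and 97.4. Leaving out the probe set numbers around the low genes left 109 of 528 genes of chromosome 4 and 3 of 340 of chromosome 13, with shifts of 0.0060 and 0.043, the opposite sign.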

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

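Of the tests in this part, those of array position and chromosome loss for the low genes, and those of array scaling and labelled rRNA for the ribosomal RNA, were chosen after the result was seen. With 2 arrays in 1 group, samples far from others and differences between groups could not be looked for, and loss of a chromosome was the only biological explanation tested. Of the 2771 probe sets outside the gene comparisons, with several genes or none named here, 2294 lay above the highest mouse control on both arrays. Of all 9335 probe sets, 8997 on replicate 1 and 8760 on replicate 2 lay above it. Opposite-strand E. coli controls read up to 3.39 and 4.07, so the count does not show how many of the 2771 gave signal.

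A control probe set for 25S ribosomal RNA read 64.2 on replicate 1 and 423 on replicate 2, a log2 ratio of 2.72, and a probe set of RDN25-1 had 2.73. Over 21 ribosomal RNA probe sets above the mouse controls the log2 ratios ran from -0.49 to 2.73, with a median of 0.19. Array scaling moves all probe sets alike and is argued against: the median of all kept genes was -0.023, and 95% of medians of 21 other probe sets matched on signal lay between -0.12 and 0.070, although probe sets of the same RNA are not independent. Array position stays open, since the 9 control probe sets, of which 8 were higher, carry no number. The 12 numbered probe sets, with 7 higher, spread widely. A probe set of RDN25-1 had 2.73 and a probe set of RDN37-1 had 1.57, while the lowest, of RDN5-3, had -0.49. Their median, 0.035, hardly shows the rise, so the median of the 25 numbered neighbours of all 12, -0.19, decides nothing. More labelled ribosomal RNA in replicate 2 also stays open: 71.4% of the probe sets (15 of 21) were higher on replicate 2, short of the share set for it and above the share that would exclude it.

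The 20 genes at least 2-fold lower on replicate 2, among them ERG29, SUP35 and RPS29B, have probe sets in 2 stretches of numbers, which largely follow the chromosomes, so the stretches alone do not separate array from chromosome. Log2 ratios of probe sets 69 to 71 numbers apart had a mean correlation of 0.155, against at most 0.0187 at the distances set for comparison, 20 to 50 and a range beyond 71, but distances of 1, 2 and 13 also had 0.228, 0.116 and 0.0981. The 71 probe sets 69 to 71 numbers from the low genes had a median 0.157 below that of 525 probe sets 20 to 50 numbers away (difference -0.16, 95% of random draws -0.044 to 0.035). A local fault on an array could give these values, as a hypothesis: the layout was inferred from these same values, and which array is affected is open. Loss of a chromosome is argued against by the medians of chromosomes 4, 12 and 13, of which the lowest was -0.084, far above the -0.5 set for a loss.

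The ribosomal protein, nuclear oxidative phosphorylation and mitochondrial ribosome lists were picked for weighing from the 5 low lists after their shifts were seen. Array position stays open: 3 of the 3 shifts stayed below the random range after correction by neighbouring probe sets, but this does not decide. The correction left out adjacent numbers, whose log2 ratios had a correlation of 0.228, and most of the low genes also remained low after it. With the numbers around the low genes left out, the mitochondrial ribosome shift was -0.038 over 37 genes and inside, at percentile 4.88. The ribosomal protein and nuclear oxidative phosphorylation shifts then stayed below the random range, so those numbers alone do not account for them. Gene length is argued against for 2 of the 3, while the mitochondrial ribosome shift went from -0.047 to -0.036 and returned inside at percentile 3.68, so length stays open there. The 3' to 5' ratios of ACT1, SPT15 and SRB4 were higher on replicate 2. A stronger 3' bias of replicate 2 was predicted to lower long genes, but the Spearman correlation of log2 ratio and gene length across 4242 genes was 0.0528 (two-sided permutation p = 0.0004, genes not being independent). Where the probes lie along each gene was not known here, so this correlation does not decide on 3' bias. A difference between the 2 cultures stays open and was not tested.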

How the results depend on the processing

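No paired analysis was possible because there is 1 group of 2 arrays, and leaving out a replicate gives no value for a difference between replicates. The settings without the probe set numbers around the low genes, with the neighbour, gene length and poly-A corrections and with a pseudocount of 1 were chosen after seeing the data. The median and SD of the log2 ratio moved by less than the replicate spread under every setting. That bound was taken from the SD itself, so it is wide for both and says little. With no filter the SD was 0.28 and the median -0.030, against 0.20 and -0.023 in the main setting. The counts of genes 2-fold higher and lower on replicate 2, 2 and 20, were 15 and 49 with no filter, 0 and 10 with the filter at the median and 1 and 8 with a pseudocount of 32, where fewer or dimmer genes or a damped scale set the count. They were 13 and 51 at 1.5-fold and 0 and 7 at 3-fold. The count of higher genes was 1 with plain probe sets and 1 with a pseudocount of 1, and that of lower genes was 0 without the numbers around the low genes, wholly by construction, since those ranges hold all 20. With the neighbour correction 14 of the 20 low genes remained. Lists below the random range, 5 in the main setting, numbered 3 with plain probe sets, and the cause was not tested. Chromosomes below and above, 5 and 4, numbered 3 below without the numbers around the low genes and 2 and 0 with the neighbour correction, where chromosome 8 stayed, 6 was new, 2, 4, 12 and 13 moved well inside, and 11, 14, 15 and 16 missed the limits narrowly at percentiles 2.54, 96.9, 97.1 and 97.4, so these counts are fragile. Without those numbers chromosomes 4 and 13 reversed to 0.0060 and 0.043, but only 109 of 528 and 3 of 340 of their kept genes were left, so these values say little about either chromosome. The lists below the random range in signal numbered 0 against filtered genes, since the filter removes their dim members. Lists above in signal numbered 16 to 17 when a replicate was left out. Of 486 list shifts under other settings, 474 kept their side of the threshold, 9 lost a place outside the random range and 3 gained it. Most lists lay inside in the main setting, and only the 5 outside could lose a place. Each of these 5 lay outside in 12 or 13 of 14 settings, the main one included. Of 221 chromosome shifts, with chromosome ends counted, 14 lost a place outside, 4 gained it and 2 reversed. Only the chromosomes outside in the main setting, 5 below and 4 above, could lose a place or reverse. List signals moved by over the replicate spread in 88 cases and by less in 159. Genes below a signal of about 19.2 varied most, with an SD of 0.45.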

Other observations

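The test of numbered probe set series in this part was chosen after several such series had been seen. Of the selectable marker genes, URA3 had 114 ± 6.40 (SD, n = 2), LEU2 140.6 ± 12.7, HIS3 140.4 ± 2.53 and MET17 843 ± 88.9, while the tryptophan gene TRP1 read 0.831 on replicate 1 and 2.16 on replicate 2, where the highest mouse controls read 0.511 and 1.30. Opposite-strand E. coli controls read up to 3.39 and 4.07, so TRP1 lay within the range of control probe sets. The 3 LEU2 probe sets disagreed, from 94.7 to 248 on replicate 1. A control probe set for URA3, not used for its value, read 232 and 226 on replicates 1 and 2, against 109 and 118. The labels name selective media but not the strain's markers. The flocculin genes FLO1 and FLO11, which give cells adhesion, had 172 ± 17.2 and 115 ± 5.05, and FLO10 had 11.01 ± 0.0823 over 7 probe sets that ran from 4.09 to 36.6 on replicate 1. HIS3 and MET17 were named after their values were seen.

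The G1/S genes CLN2, CLB5 and POL30 had 45.9 ± 3.23, 58.9 ± 1.11 and 106 ± 18.6, and 9 of 15 kept genes of the list lay above the median ratio of all kept genes, with a shift of 0.040 inside the random range. The G2/M cyclin gene CLB2 was 44.2 and 30.8 on replicates 1 and 2, CDC5 76.2 and 84.0 and SWI5 73.5 and 63.5, and 7 of 9 kept genes of the list lay below that median, with a shift of -0.018 also inside. A list of 9 genes leaves a wide random range, from -0.11 to 0.13. The ribonucleotide reductase genes RNR1, RNR2 and RNR3 had 161 ± 9.00, 449 ± 38.3 and 30.1 ± 5.73. The phosphate genes PHO84 and PHO5 had 100.4 ± 0.121 and 194 ± 4.05, and the iron genes FET3 and FTR1 450 ± 16.5 and 133 ± 11.2.

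Some genes have several consecutively numbered probe sets. For the glucan synthase gene FKS1 the first read 8.18 and 4.57 and the seventh 398 and 359 on replicates 1 and 2, with log2 ratios of -0.84 and -0.15. The hypothesis that a stronger 3' bias of replicate 2 gives this trend in other genes was tested on 69 of 74 series, leaving out FKS1, RPA190 and FLO10 and 2 series, HOB2 and VIP1, in which the log2 ratio had a rank correlation of 0 with the number. Signal increased with the number in 61 of them, but the log2 ratio did so in 40, or 58.0% (exact two-sided sign test p = 0.228), so the test decided nothing. It rests on the assumption that numbers run from 5' to 3', which the files do not state, and other series had been looked at before it was set.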
